A study of Homo sapiens with 12 samples.

How the data were processed

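RNA-seq libraries of CD133(+) and CD133(−) cells of Saos-2, an established human osteosarcoma line, were compared. The sample titles call the cells of both groups osteosarcoma stem cells. The 12 samples form 4 groups of 3, with replicates numbered 4 to 6 for the gene (mRNA) tables and 1 to 3 for the lncRNA tables. Each deposited table held whole-number counts per gene or per lncRNA transcript, not normalised, and beside them FPKM values, which the authors had scaled by feature length and library total. HISAT2, StringTie and GRCh38 are named for the upstream work per the submitters' processing notes, and their versions and settings are not given in the sources used here. The gene tables had 58302 rows with symbols, and the lncRNA tables had 66460 transcript rows, of which 12827 carried Ensembl, 51536 NONCODE and 2097 assembled-transcript identifiers. The strand setting of the counting is not given, so reads of overlapping or antisense features cannot be told apart and such features are uncertain.

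The lncRNA rows carried no gene name. An Ensembl transcript was given the symbol of a non-coding gene when its span lay inside exactly 1 such locus of the gene table, which placed 9539 transcripts in 6592 loci. The transcript and gene tables were then compared at 1502 loci of identical span. In the best-matching pairs of a lncRNA table and a gene table, 67.5% to 71.6% of these loci differed by at most 1 count, against 1.60% to 12.98% in the other pairs. The matches paired number 1 with 4, 2 with 5 and 3 with 6 within each group. The tables were therefore treated as counts of the same 6 libraries, and the lncRNA and gene results are not independent.

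Totals ranged from 13142932 to 23152734 counts in the gene tables and from 2283685 to 11000754 in the lncRNA tables. Counts were tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood test, TMM factors, filterByExpr, no block), with Benjamini-Hochberg adjusted p under 0.05 as the threshold, two-sided. CPM values are normalised to the TMM-scaled library total. Log2 fold changes are CD133(+) over CD133(−), and the standard error is the fold change divided by the square root of the F statistic. Gene lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01 on log2 CPM with a prior count of 2. The 38 lists held 888 entries, 854 of which matched the gene table, through RefSeq symbols and synonyms where the table's own name differed. Lists with fewer than 5 tested genes were not tested. The lists, tests and naming rule were fixed before the data were examined.

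The naming rule took, where nothing passed the threshold, the 10 features with the smallest p in each direction that had a gene symbol, groups that did not overlap and a mean of at least 50 counts in the higher group. PROM1 was always named, as were up to 4 members of each list with the smallest p and the 5 lncRNA and partner pairs with the smallest lncRNA p. A gene that the rule names is not reported here. Genes named from the paired fits were chosen after their values were seen.

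Replicate numbers were checked for pairing before any fits were compared. Deviations from the group means correlated between the CD133(+) and CD133(−) libraries of the same number at 0.773, 0.646 and 0.581 in the gene tables and at 0.536, 0.328 and 0.264 in the lncRNA tables, all above the 0.1 taken as pairing. These values carry mainly the distance of number 4 (and 1) from the others, which also sets the deviations of the others from the group means. The difference between numbers 5 and 6 correlated between CD133(+) and CD133(−) libraries at 0.121 across genes, and that between numbers 2 and 3 at 0.0327 across transcripts, so pairing among these numbers was weak or not seen. The pairing comes from these data and the numbers in the labels, which do not say what a number shares. Nothing in the labels says that replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical.

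Alternative settings chosen beforehand were the replicate block, DESeq2 1.42.0, median-of-ratios factors, no low-count filter, a filter of at least 50 counts in 3 libraries, limma on log2(FPKM + 0.1), library quality weights, at least 2-fold, each library left out, camera with an estimated correlation, fry, other sets of antisense pairs, and only genes above the median mean expression for the correlation between tables. DESeq2 with the replicate block, camera with an estimated correlation and the block, and fits without the libraries numbered 4 and 1 were added after the data were seen.

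The fits were tested on simulated data with 200 features changed by known folds, drawn from the means, library sizes and paired dispersions of these libraries. The means were fitted by replicate number, so both libraries of a number shared them before the known changes. Pairing was thus built into the simulation. The gain of the block over no block follows from this and does not show that the real libraries are paired. Over 16823 simulated genes, edgeR without the block recovered 0% of 2-fold, 4% of 4-fold, 38% of 8-fold and 70% of 16-fold changes, with 0 unchanged genes called. edgeR with the block recovered 50%, 80%, 100% and 98% of the same sizes, with 26 of its 192 calls unchanged genes. DESeq2 without the block recovered 6%, 54%, 98% and 96%, with 2 of 129 calls unchanged, and DESeq2 with the block 56%, 80%, 96% and 98%, with 21 of 189. Over 11248 simulated lncRNA transcripts, edgeR without the block recovered 0% at each size and edgeR with the block 0%, 0%, 14% and 30%, with 1 of 24 calls unchanged. DESeq2 without the block recovered 0%, 10%, 50% and 62%, with 16 of 78 calls unchanged, and DESeq2 with the block 2%, 8%, 64% and 70%, with 32 of 105. Camera was run on a simulated list of 30 genes shifted by 0.5 in log2. Its unadjusted p was 7.31e-15 at the preset correlation and 0.00613 with an estimated one. For 30 unchanged genes these were 0.587 and 0.571. For 30 shifted lncRNA transcripts they were 6.47e-05 and 0.0105, and for 30 unchanged ones 0.277 and 0.351.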

Results

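Gene and lncRNA transcript counts were obtained for Saos-2 cells, a human osteosarcoma line, separated by CD133, the membrane glycoprotein encoded by PROM1 that is widely used as a marker of stem-like tumour cells. The comparison asked which mRNAs and lncRNAs differ between CD133(+) and CD133(−) cells, with 3 libraries in each group. As the titles name both groups osteosarcoma stem cells, the labels do not set stem cells against other cells of the line. Gene-table totals were 17978797, 16706835 and 13142932 counts in CD133(−) libraries 4, 5 and 6, and 23152734, 15916065 and 14949518 in CD133(+) libraries 4, 5 and 6. The lncRNA tables, which count the same libraries under numbers 1, 2 and 3, held 6928273, 2575323 and 2283685 counts in CD133(−) and 11000754, 2734353 and 2405801 in CD133(+) libraries.

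The libraries numbered 4 stood apart from the rest in both groups. The abundant small RNAs RN7SL1, RN7SL2, RN7SK, RPPH1 and RMRP took 53.5% of counts in the CD133(−) and 49.6% in the CD133(+) library numbered 4, against 10.9% to 11.6% in the other 4 libraries. The nuclear lncRNA MALAT1 held 0.0193% and 0.0362% of counts in the libraries numbered 4 and 0.316% to 0.377% in the others. Correlations of log2 CPM were 0.879 to 0.895 between number 4 and the others, and 0.978 to 0.984 among the others.

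**Figure D1:**
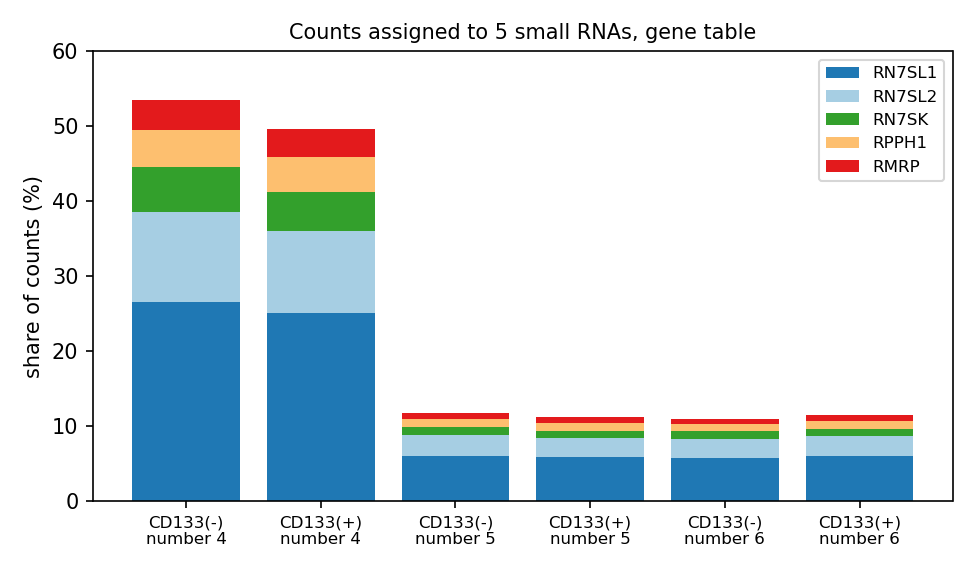
Share of gene-table counts (%) assigned to 5 small RNAs in each library, stacked by RNA. The bars reach 53.5% and 49.6% in the libraries numbered 4 and 10.9% to 11.6% in those numbered 5 and 6.

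PROM1 (ENSG00000007062, GRCh38 chromosome 4, 15963076 to 16084378) was measured at 3.02 ± 0.519 CPM (SD, n = 3) in CD133(−) and 10.6 ± 6.22 CPM (SD, n = 3) in CD133(+) libraries. The log2 fold change was 1.82 (SE 0.51), with log2 ratios of 0.45, 2.74 and 1.59 in the pairs numbered 4, 5 and 6. It did not pass the threshold over all genes in edgeR's quasi-likelihood test (adjusted p = 1). An exact two-sided permutation test gave p = 0.1, the smallest that 3 against 3 libraries allow. Counts of PROM1 were low, from 28 to 368 per library, and its locus overlaps that of FGFBP2.

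Between CD133(+) and CD133(−) cells, extracellular matrix genes were higher as a list, with 25 of 32 tested members above 0, and osteoblast differentiation genes lower, with 14 of 16 below 0 (camera adjusted p = 0.00232 and 0.0237). Both calls were lost with an estimated correlation (adjusted p = 0.208 and 0.682) and without the CD133(−) library numbered 4 (adjusted p = 0.118 and 0.737). Without that library the osteoblast genes ALPL and SP7 turned in the unpaired test, though both were below 0 in each of the 3 pairs. Of 35 lists tested 10 passed at the preset correlation, and 11 did when the same libraries were split in another way. NES, the neural progenitor filament nestin, and the aldehyde dehydrogenase ALDH1A1 were above 0 and ALDH1A3 below 0 in each of the 3 pairs. Each of these genes, ALPL and SP7 included, passed with the replicate block when adjusted over its list alone. Passing such a fit favours the same sign in all pairs, so the shared signs are no further support. No single gene passed the threshold in the unpaired edgeR test: 0 of 16823 genes, with 159 at an unadjusted p under 0.05. Those were 0.945% of genes, below the share of 0.05 that unchanged genes would give, so the unpaired test was conservative here. edgeR with the replicate block also called 0 genes, with 1266 at an unadjusted p under 0.05, DESeq2 without the block called 3, including MYH3 and the clone-named gene AC007240.1, which overlaps RRM2 so that its reads are uncertain, and limma on log2 FPKM called 0. DESeq2 with the replicate block, added after the data were seen, called 61 genes, 36 higher and 25 lower in CD133(+) cells, and DESeq2 without the libraries numbered 4 called 130. When the same libraries were split in the other ways that part each pair, the blocked DESeq2 fit called 12, 14 and 13 genes. On simulated data 21 of its 189 calls were unchanged genes, so some of the 61 may be false.

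Genes with the smallest p among those higher in CD133(+) cells, none past the threshold in the unpaired edgeR test, included MYH3, LINC00355, COL4A1, EMILIN1, IGFN1, GPR55, WFDC21P, VSIR and MTMR11. MYH3, the embryonic myosin heavy chain, was at 18.6 ± 4.66 CPM in CD133(−) and 64.4 ± 17.4 CPM in CD133(+) libraries (SD, n = 3), a log2 fold change of 1.79 (SE 0.34, edgeR adjusted p = 1). It passed in DESeq2 without the block (adjusted p = 0.0135) and with library quality weights (0.0368). COL4A1, a basement membrane collagen chain, had a log2 fold change of 1.38 (SE 0.32), and EMILIN1, an elastic fibre glycoprotein, one of 1.35 (SE 0.34). The lncRNA LINC00355 was at 1.73 (SE 0.36), IGFN1 at 1.89, GPR55, a G protein-coupled receptor, at 1.35, WFDC21P at 1.13, the immune checkpoint receptor VSIR at 1.10 and MTMR11 at 1.32. IGFN1 had log2 ratios of 2.95, 1.52 and 0.77 in pairs 4, 5 and 6 and fell as low as 1.28 with a library left out. VSIR lies within the CDH23 locus, so its reads are uncertain. In DESeq2 with the block, MYH3 (adjusted p = 4.98e-16), COL4A1 (6.24e-06), EMILIN1 (1.37e-05), VSIR (0.00263), LINC00355 (0.0195), MTMR11 (0.0468) and PROM1 (0.0395) passed.

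The 10 lower in CD133(+) cells by the same rule, again none past the threshold in the unpaired edgeR test, were SELENOT, ZNF672, SLC35A5, CD59, TICAM2, RWDD2B, TADA2B, ZNF84, PSME3 and SMG8. SELENOT, a selenoprotein of the endoplasmic reticulum, was at 73.1 ± 6.02 CPM in CD133(−) and 37.1 ± 3.67 CPM in CD133(+) libraries (SD, n = 3), a log2 fold change of −0.98 (SE 0.26, edgeR adjusted p = 1). The zinc finger gene ZNF672 had a log2 fold change of −2.29 (SE 0.62) and pair ratios of −2.01, −2.53 and −2.64. CD59, an inhibitor of the complement membrane attack complex, was at −1.34 (SE 0.38), and its ratio was −0.43 in pair 4 but −1.81 and −1.50 in pairs 5 and 6. TICAM2 was at −2.48, with pair ratios of −1.97, −0.11 and −3.75, and at −1.42 without the CD133(−) library numbered 6, and it overlaps the read-through gene TMED7-TICAM2 and its reads are uncertain. SLC35A5 was at −0.96, RWDD2B at −0.99, TADA2B at −1.08, ZNF84 at −1.05, the proteasome activator subunit PSME3 at −1.22, or −0.72 without the CD133(−) library numbered 4, and SMG8, a factor of nonsense-mediated decay, at −1.29. SELENOT overlaps SERP1, SLC35A5 overlaps ATG3, CD59 overlaps C11orf91 and PSME3 overlaps BECN1, so their reads are uncertain. ZNF672 (adjusted p = 6.84e-16), SELENOT (2.22e-06), ZNF84 (0.000618), CD59 (0.00216), SMG8 (0.0213), SLC35A5 (0.0224) and PSME3 (0.0485) passed in DESeq2 with the block. With library quality weights ZNF672 (adjusted p = 0.00285), CD59 (0.0109) and SELENOT (0.0368) passed.

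Genes outside the naming rule were also among the 61 calls of DESeq2 with the block, and the following were picked after their values were seen. Higher in CD133(+) cells were the cell adhesion gene NLGN4X (log2 fold change 1.73, SE 0.25), the protease inhibitor A2M (1.22, SE 0.17), the chemokine CXCL14 (1.58, SE 0.26), the GDNF family receptor GFRA1 (1.95, SE 0.40) and the cyclin CCND1 (1.29, SE 0.33). Also higher were AHNAK2 (1.05), EMP1 (1.37), the glycoprotein GPNMB (0.77) and the microfibril gene MFAP5 (1.25). Lower were the adhesion receptor ADGRL2 (−0.88, SE 0.15), the matrix-associated membrane protein LRRC15 (−0.68, SE 0.14) and the glutamine transporter SLC1A5 (−0.65, SE 0.15). SLC1A5 turned to 0.57 in the unpaired edgeR test without the CD133(−) library numbered 4. Its log2 ratios were −0.511, −0.759 and −0.682 in pairs 4, 5 and 6. In the unpaired test without the CD133(+) library numbered 5, NLGN4X was at 1.08, A2M at 0.84, AHNAK2 at 0.72 and GPNMB at 0.48. CCND1 was at 0.58 without the CD133(−) library numbered 4 and ADGRL2 at −0.57 without the CD133(+) library numbered 4. The adjusted p-values in DESeq2 with the block ran from 5.61e-09 for NLGN4X and A2M to 0.0233 for CCND1.

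**Figure D2:**
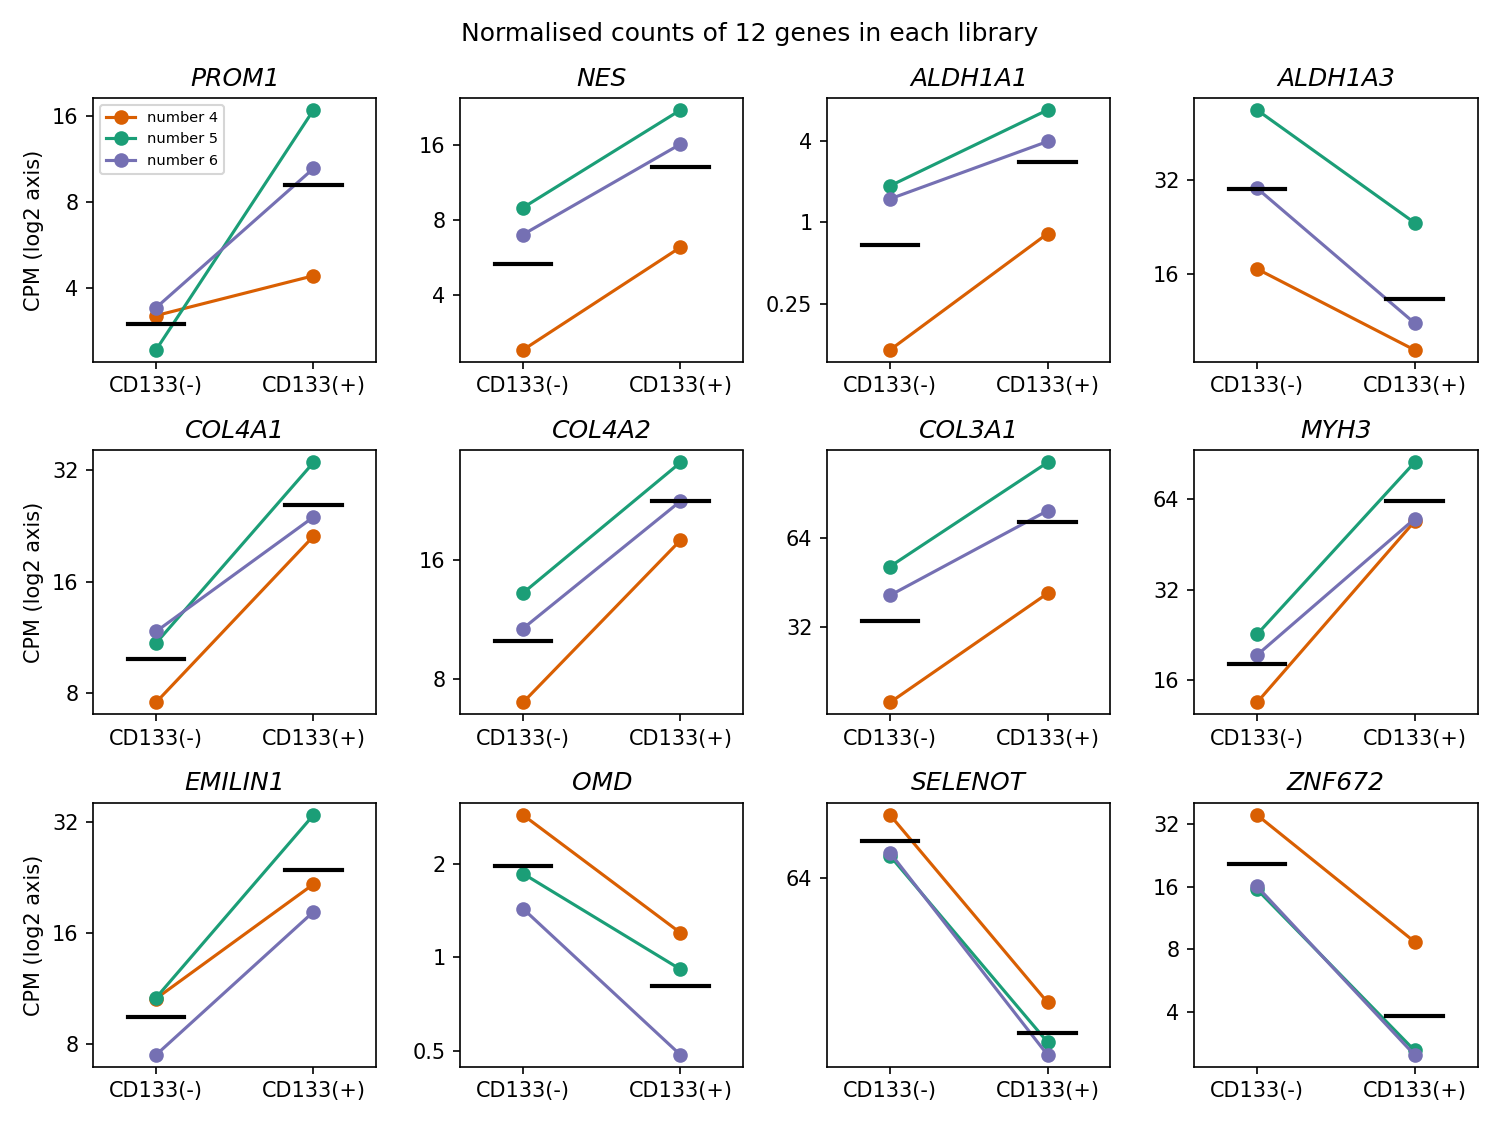
CPM (log2 axis) of 12 genes in each CD133(−) and CD133(+) library, with lines joining libraries of the same number and black bars at the geometric mean of 3 libraries. PROM1 differs by a log2 ratio of 0.45 in pair 4 and 2.74 in pair 5, while COL3A1 runs from 0.95 to 1.22 and NES from 1.20 to 1.34 over the 3 pairs.

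Among 35 gene lists tested, 10 passed camera at the preset correlation, 7 higher and 3 lower in CD133(+) cells. When the same libraries were split in other ways, up to 11 lists passed. Of all 10 splits, 2 gave as many as the real one, itself included, so the number of lists does not set CD133 apart. None of the lists passed with an estimated correlation (smallest adjusted p = 0.208) or in fry (smallest adjusted p = 0.406). A simulated list of 30 genes shifted by 0.5 in log2 reached only p = 0.00613 in camera with an estimated correlation, before any adjustment over lists. A call lost in that test is therefore weak evidence that a list is unchanged. The simulated genes were drawn at random and varied independently around their means, so this holds for lists of little-correlated genes. The estimated correlation was −0.021 for the extracellular matrix list. It was 0.905 for ribosomal protein, 0.628 for mitochondrially encoded and 0.268 for osteoblast genes. For these 3 lists the preset 0.01 was far too low, so their preset p-values are not reliable. No list member passed over all genes, or adjusted over the list alone, in the unpaired edgeR test. With the replicate block, 24 memberships passed when adjusted over the list alone and 0 over all genes. Leaving out the CD133(+) library numbered 5 reduced the lists past the threshold from 10 to 6. Of the 10, the mitochondrially encoded and neural progenitor lists kept their calls at the preset correlation whichever library was left out. Their highest adjusted p-values in these camera tests were 0.0143 and 0.0498, the latter just under the threshold and on 7 tested genes.

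The extracellular matrix list was higher in CD133(+) cells, with 25 of 32 tested members above 0 (camera adjusted p = 0.00232, and adjusted p = 0.208 with an estimated correlation). With the block, 9 members passed adjusted over the list alone, all higher: COL3A1, COL4A1, COL4A2, LAMA4, TIMP3, COL12A1, DCN, FBN2 and FN1. COL4A2 had a blocked log2 fold change of 1.17 (SE 0.13), the fibrillar collagen COL3A1 one of 1.11 (SE 0.12), the proteoglycan DCN one of 1.07 (SE 0.26) and fibronectin, FN1, one of 0.40 (SE 0.11), though unblocked FN1 was near 0 without the CD133(−) library numbered 4 (0.005) or the CD133(+) library numbered 5 (0.056). The list's call was lost without the CD133(−) library numbered 4 (adjusted p = 0.118), and TIMP3, at 0.55 with the block, turned to −0.04 without the CD133(+) library numbered 5. COL3A1 was at 0.71 in the unpaired test without that CD133(+) library. In the same test with a library left out, COL12A1 fell as low as 0.12, FBN2 0.19 and LAMA4 0.37. All 9 members were above 0 in each pair, which passing with the block favours, so this is no further support. COL4A1 and COL4A2 loci overlap each other at their ends. TGFBI (0.55, SE 0.10) of the mesenchymal list and LTBP2 (1.14, SE 0.19) of the TGF-beta and BMP list, both matrix proteins, also passed adjusted over their lists alone, while neither list passed (camera adjusted p = 0.703 and 0.66).

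Of the cancer stem cell markers, 12 of 22 tested members were above 0 and the list did not pass (camera adjusted p = 0.423). With the block, 4 members passed adjusted over the list alone. NES, the intermediate filament nestin, was at 1.28 (SE 0.14), ALDH1A1 at 1.74 (SE 0.29) and PROM1 at 1.73 (SE 0.44), whereas ALDH1A3 was lower at −1.18 (SE 0.15). ALDH1A1 counts were as low as 1 in the CD133(−) library numbered 4. In the unpaired test ALDH1A1 was at 1.00 without the CD133(+) library numbered 5 and ALDH1A3 at −0.67 without the CD133(−) library numbered 5. The neural progenitor list passed (7 tested, camera adjusted p = 0.00147, and adjusted p = 0.208 with an estimated correlation), with 6 of 7 members above 0, among them NES and the neuronal microtubule protein MAP2 (0.93, SE 0.59). MAP2 had ratios of 0.003, 1.45 and 0.63 in pairs 4, 5 and 6 and was at 0.28 without the CD133(+) library numbered 5.

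The osteoblast differentiation list was lower in CD133(+) cells, with 14 of 16 tested members below 0 (camera adjusted p = 0.0237, and adjusted p = 0.682 with an estimated correlation). With the block, OMD, which encodes osteomodulin of mineralised matrix, was at −1.25 (SE 0.27), at 10 to 42 counts per library and within the CENPP locus, tissue-nonspecific alkaline phosphatase, ALPL, at −0.50 (SE 0.12) and SP7, the osteoblast transcription factor osterix, at −0.47 (SE 0.11). These 3 passed adjusted over the list alone. In pairs 4, 5 and 6 the log2 ratios were −0.375, −0.401 and −0.726 for ALPL and −0.532, −0.400 and −0.473 for SP7. Without the blocked design, leaving out the CD133(−) library numbered 4 turned ALPL and SP7 to 0.14 and 0.39. That fit keeps the CD133(+) library numbered 4 without its partner, so the distance of number 4 from the others enters the difference. The list's call was lost without the CD133(−) library numbered 4 (adjusted p = 0.737). It was also lost without the CD133(+) library numbered 5 or 6 (0.0576 and 0.24) and without both libraries numbered 4 (0.185).

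The 13 mitochondrially encoded mRNAs were higher as a list (camera adjusted p = 9.81e-12, and adjusted p = 0.333 with an estimated correlation), with all 13 above 0. Their median log2 ratio was 2.87 in pair 4 and 0.24 and 0.09 in pairs 5 and 6, and MT-ND1 had a ratio of 3.37 in pair 4 and a log2 fold change of 0.43 without the CD133(+) library numbered 4. They made up 0.213% of counts in the CD133(−) and 1.46% in the CD133(+) library numbered 4, and 0.831% to 1.03% in the others. All 54 cytosolic ribosomal protein genes were lower, with a median log2 fold change of −0.29 (camera adjusted p = 2.86e-05, and adjusted p = 0.831 with an estimated correlation). Their pair medians were −0.52, −0.24 and −0.11, with RPL7 at −0.65 and RPS6 at −0.43, or −0.17 and −0.22 without the CD133(−) library numbered 4. Without the CD133(−) library numbered 4, the direction of this list turned and it no longer passed (adjusted p = 0.109), nor did it without the CD133(+) library numbered 5 (0.203) or 6 (0.138).

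Drug efflux ABC transporters were higher, with 12 of 13 members above 0 (camera adjusted p = 0.00109, and adjusted p = 0.208 with an estimated correlation), including the cholesterol exporter ABCA1 at 0.62 (SE 0.32), and lost the call without the CD133(+) library numbered 4 (0.198). Interferon response genes passed as higher although 11 of 21 members were above 0 (camera adjusted p = 0.00694, and adjusted p = 0.208 with an estimated correlation). Their leading members were the antiviral genes OAS2 at 0.98 (SE 0.36), OAS1 at 0.89 (SE 0.39) and MX1 at 0.61 (SE 0.30). The interferon call was lost without the CD133(−) library numbered 4 (0.057) or 5 (0.0553) or the CD133(+) library numbered 5 (0.127). Cholesterol biosynthesis genes were lower, with 20 of 21 below 0 (camera adjusted p = 0.011, and adjusted p = 0.419 with an estimated correlation), such as squalene epoxidase, SQLE, at −0.57 (SE 0.33) and HMGCS1 at −0.43 (SE 0.46), or −0.11 without the CD133(+) library numbered 4. That call was lost without the CD133(−) library numbered 4 (0.601) or 6 (0.125), the CD133(+) library numbered 4 (0.174) or 5 (0.203), or both numbered 4 (0.0565). The IGF and insulin list had 13 of 16 members above 0 (camera adjusted p = 0.0357, and adjusted p = 0.333 with an estimated correlation). With the block its binding proteins went apart, with IGFBP3 at 0.66 (SE 0.13) and IGFBP5 at −0.49 (SE 0.11), both past the threshold adjusted over the list alone. In the unpaired test IGFBP3 was at 0.39 without the CD133(−) library numbered 4 and IGFBP5 at −0.07 without the CD133(+) library numbered 4. The IGF call held only without the CD133(−) library numbered 6, and adjusted p was 0.0635 to 0.317 without any other library and 0.255 without both numbered 4. Epithelial markers had 7 of 9 members above 0 (camera adjusted p = 0.0405, and adjusted p = 0.343 with an estimated correlation), with KRT8 at 0.33 (SE 0.34), or 0.09 without the CD133(+) library numbered 4. CDH1 was at 0.82 (SE 0.80), with a ratio of 4.14 in pair 4 against 0.32 and −0.66 in pairs 5 and 6. The epithelial call was lost without the CD133(−) library numbered 4 (0.259) or 5 (0.131), the CD133(+) library numbered 4 (0.555) or both numbered 4 (0.545). The remaining 25 lists, which included the S phase and G2/M phase lists, pluripotency factors and Wnt, Notch and Hedgehog signalling, had adjusted p-values of 0.0873 or more. With the block, 13 lists passed, the 10 above and Notch signalling (adjusted p = 0.0365), nuclear oxidative phosphorylation (0.0182) and small nucleolar RNA hosts (0.0121), and 0 passed with the block and an estimated correlation. Without the libraries numbered 4, the G2/M list was higher (adjusted p = 0.0254) and small nucleolar RNA hosts lower (0.0373) at the preset correlation, and neither passed with an estimated one (adjusted p = 0.928 for each).

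**Figure D3:**
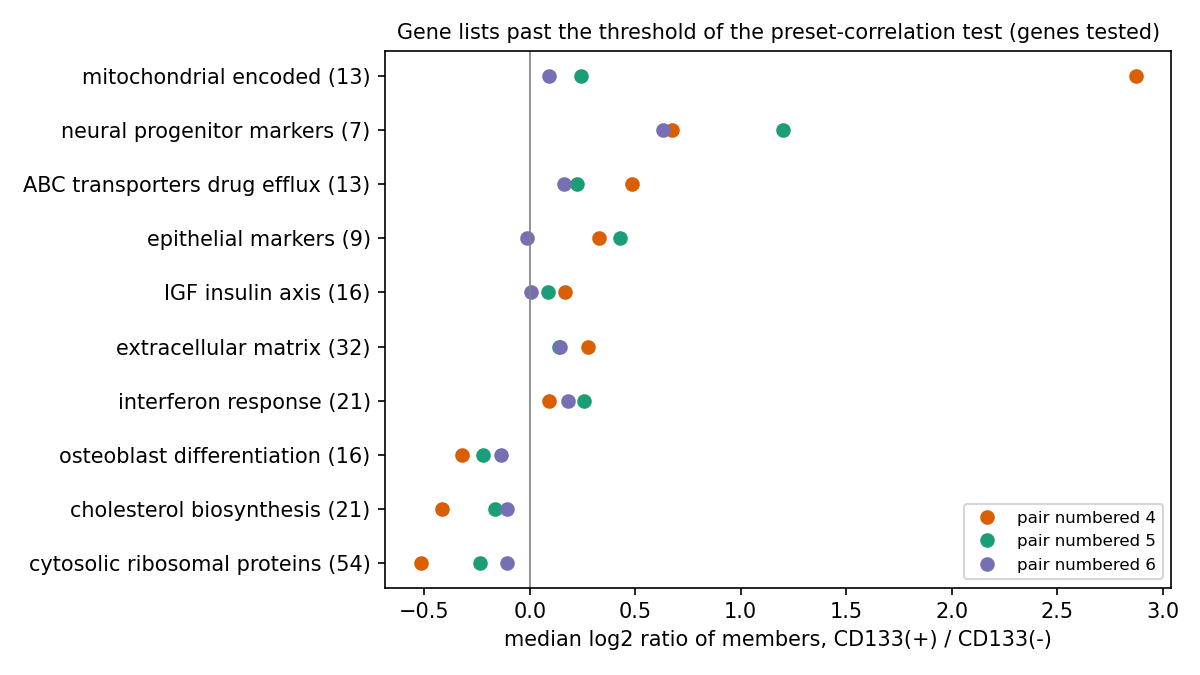
Median log2 ratio, CD133(+) over CD133(−), of the members of the 10 lists past the preset-correlation threshold, with 1 point for each pair of libraries and the number of tested genes in brackets. The mitochondrially encoded list lies at 2.87 in pair 4 and at 0.24 and 0.09 in pairs 5 and 6.

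Among lncRNA transcripts, a NONCODE transcript in the PLEKHA8 locus was lower and one in the DDR1 locus higher in CD133(+) cells in the paired DESeq2 fit. That fit called 27 transcripts, and 26, 20 and 20 when the same libraries were split in the 3 other ways that part each pair, and 32 of its 105 calls on simulated data were unchanged transcripts. In edgeR's test 0 of 11248 transcripts passed, with 135 (1.2%) at an unadjusted p under 0.05, again below the share that unchanged transcripts would give. The replicate block also gave 0, limma on log2 FPKM gave 0, and DESeq2 called 16, with 5 higher and 11 lower. The 27 of DESeq2 with the block were 9 higher and 18 lower. NONHSAT119847.2, inside the PLEKHA8 locus on chromosome 7 (30081089 to 30084649), was at 58.0 ± 13.02 CPM in CD133(−) and 1.97 ± 0.197 CPM in CD133(+) libraries (SD, n = 3). Its log2 fold change was −4.85 (SE 0.46, edgeR adjusted p = 0.242), and it passed with the stricter count filter (adjusted p = 0.0219). NONHSAT207087.1, inside the DDR1 locus on chromosome 6 (30898998 to 30900091), went the other way at 5.62 (SE 0.70, edgeR adjusted p = 0.651). Both transcripts were picked after their values were seen, and reads of their host genes could not be separated from theirs.

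By the naming rule 4 transcripts were found, none past the threshold. ENST00000421685, in ZNF674-AS1, was higher at 1.12 (SE 0.52, adjusted p = 1), ENST00000504184, in LINC01521, was at −0.97 (SE 0.47, pair ratios −1.55, −0.49 and −0.60), ENST00000567819, in CAPN10-DT, at −2.40 (SE 1.31) and ENST00000436786, in LINC01239, at −1.33 (SE 1.20). The last 2 had 0 counts in the CD133(+) library numbered 1, and CAPN10-DT had ratios of −0.35 and −0.45 in pairs 2 and 3. Without the CD133(−) library numbered 1, LINC01521 was at −0.53 and CAPN10-DT at −0.94, and without the CD133(+) library numbered 1 LINC01239 was at −0.75. In the gene tables, BANCR of the cancer lncRNA list was at 1.10 (SE 0.19) and DANCR at −0.81 (SE 0.17) with the block, both past the threshold adjusted over the list alone. DANCR turned to 0.19 in the unblocked test without the CD133(−) library numbered 4, while its log2 ratios were −0.894, −0.438 and −1.065 in pairs 4, 5 and 6.

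Transcripts of small nucleolar RNA host genes were lower in CD133(+) cells, with 39 of 48 below 0 and a median log2 fold change of −0.31 (camera adjusted p = 0.0172, and adjusted p = 0.825 with an estimated correlation). That correlation was 0.592, far above the preset 0.01, so the preset p-value is not reliable. The list lost its call without the CD133(+) library numbered 2 (0.652) or 3 (0.474), and turned to higher without the CD133(−) library numbered 1 (adjusted p = 0.0482). Cancer-associated lncRNAs and microRNA host transcripts did not pass (adjusted p = 0.597 for each). Without the libraries numbered 1, cancer-associated lncRNAs were lower (adjusted p = 0.000765) and microRNA hosts higher (0.0394) at the preset correlation, and neither passed with an estimated one (adjusted p = 0.109 and 0.148).

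The co-expression of lncRNAs with neighbouring mRNAs was examined in 102 pairs of an antisense or divergent lncRNA and its partner gene. The correlation of log2 fold changes across pairs was r = 0.172 (permutation p = 0.0836) and rho = 0.183 (permutation p = 0.0672), and genes are not independent replicates. It was r = 0.248 (permutation p = 0.0395) over the 70 pairs with antisense names and r = 0.004 (permutation p = 0.926) over 586 pairs with no low-count filter. The 5 pairs with the smallest lncRNA p had lncRNAs THAP9-AS1 at 1.84, ZSWIM8-AS1 at 1.17, ZNF674-AS1 at 1.12, MCM3AP-AS1 at 2.42 and SLC25A25-AS1 at 2.48, none past the threshold. Their partners were THAP9 at 0.35, ZSWIM8 at 0.24, ZNF674 at 0.29, MCM3AP at 0.19 and SLC25A25 at −0.28. Without the libraries numbered 1 and 4, the correlation turned to r = −0.233 (permutation p = 0.0214) with rho = 0.078 over 118 pairs. Across 1202 non-coding genes measured in both kinds of table, log2 fold changes correlated at r = 0.611 and rho = 0.802 (permutation p = 1e-05 for each, the smallest that the permutations can give), and 86.9% had the same sign. Over the 601 with the higher mean expression r was 0.49 and rho 0.758. With Benjamini-Hochberg adjustment over the 2 families, the p-values of r were 0.0836 and 2e-05. Both kinds of table count the same libraries, so this compares 2 quantifications.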

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

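Fits without the libraries numbered 4 and 1, and those joining DESeq2 or an estimated correlation with the block, were chosen after the data were seen. The count of changed genes, 0 in edgeR, stayed 0 under the replicate block, other scaling factors, both filters, limma on FPKM and each left-out library (lowest and highest 0), and became 3 with DESeq2, 12 with quality weights, 3 without number 4 (0 with the block there), 61 with DESeq2 and the block and 130 with DESeq2 without number 4. The lncRNA count, also 0 with the replicate block and each left-out library, became 16 with DESeq2, 1 with the stricter filter, 2 with quality weights, 27 with DESeq2 and the block and 122 with DESeq2 without number 1. PROM1 was at 1.73 with the replicate block (adjusted p = 0.647), from 1.31 to 2.18 with a library left out, and past the threshold at 1.67 with DESeq2 and the block (adjusted p = 0.0395) and at 2.23 with DESeq2 without number 4 (6.08e-07), the range over its alternatives reaching adjusted p = 1. The 10 gene lists became 13 with the replicate block, 0 with an estimated correlation with or without the block or number 4, 0 with fry, and 6 to 13 with a library left out. The 1 lncRNA list stayed 1 with the block and became 0 with an estimated correlation with or without it or number 1, 0 with fry, 3 without number 1 with or without the block, and 0 to 2 with a library left out. The pair correlation was 0.248 for antisense names alone, 0.004 with no low-count filter, 0.103 with the block, and −0.233 without numbers 1 and 4; the correlation between tables was 0.49 above the median expression and ran from 0.531 to 0.768 with a library left out. Without the CD133(−) library numbered 4, the directions of ribosomal protein genes (adjusted p = 0.109; 8.97e-12 to 0.203 over left-out libraries), nuclear oxidative phosphorylation genes (0.0176; 0.000315 to 0.942), histones (0.000129; highest 0.263) and small nucleolar RNA hosts (0.0418; 1.27e-05 to 0.993) turned, as did the latter in the lncRNA table without number 1 (0.0482; 8.99e-10 to 0.652). So did ALPL (0.14, lowest −1.14), SP7 (0.39, lowest −1.33), DANCR (0.19, lowest −1.86) and SLC1A5 (0.57, lowest −1.87), although each of these genes was below 0 in all 3 pairs. TIMP3 turned to −0.041 without CD133(+) number 5, its highest being 1.15. CDH1 turned to −0.089 with quality weights, and without number 4 to −0.24, −0.19 with the block and −0.25 with DESeq2. A left-out library also unbalances the pairs. Without CD133(−) number 4 its CD133(+) partner stays in, so the distance of number 4 from the others enters the unpaired difference. The turns of ALPL, SP7, DANCR and SLC1A5 came from such a fit and were seen in no pair. These genes were named after passing a fit with the block, which favours the same sign in all pairs. All 61 calls of DESeq2 with the block had 1 sign in the 3 pairs. The pair signs are therefore no independent evidence against the turns. Beyond the unbalanced pairs, the cause was not tested for any of these changes. Named genes and transcripts kept direction and side of the threshold in 1127 other comparisons and newly passed in 72. Added to edgeR on all 6 libraries and to camera at the preset correlation, the block changed calls of single lists but not of PROM1 or the counts of changed genes and lncRNAs; added to DESeq2 it raised those counts and called PROM1. Pseudocount and quantile alternatives applied only without counts, transcript or gene level regrouping had no identifiers, and pairs with a lncRNA at p under 0.05 were too few. In the shallower lncRNA tables simulated 2-fold changes were recovered at 0% by edgeR and 2% by DESeq2 with the block; the part of depth was not separated from that of dispersion, and unblocked edgeR also recovered 0% in the gene tables.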

Other observations

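The tests of FGFBP2, of coding loci and of the splits without the block were chosen after the results they measure were seen. The 15 immune markers summed to 3.34 to 12.1 CPM in each library, the 11 erythroid and platelet genes to 0.73 to 2.45 the 12 endothelial markers to 16.1 to 35.9, the 10 adipocyte markers to 32.8 to 49.3 and the 18 epithelial markers to 55.8 to 171. Among endothelial markers, the receptor KDR had a log2 ratio of 2.17 in pair 4 and −0.18 and −1.51 in pairs 5 and 6. The 16 chondrocyte markers summed to 288 and 374 in the CD133(−) and CD133(+) libraries numbered 4 and to 1089 to 1266 in the others. The TMM factors were 0.486 and 0.577 in the libraries numbered 4 and 1.36 to 1.38 in the others, so the size of this gap depends on the scaling. The small heat shock protein HSPB1 was at 0.66 (SE 0.13) with the block, past the threshold adjusted over its list alone, and at 0.41 in the unpaired test without the CD133(+) library numbered 4. PRNP, the prion protein gene, picked after its values were seen, was called higher by edgeR without number 4 (log2 fold change 3.09, adjusted p = 0.00628) and with quality weights (3.01, 0.00173). edgeR without number 4 and with the block called 0 genes (smallest adjusted p = 0.0549), so the first of these calls was lost. DESeq2 called PRNP without number 4 (adjusted p = 7.47e-77) but not on all libraries, with or without the block. The calls of PRNP thus come from fits that leave out number 4 or weight the libraries.

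The libraries numbered 4 correlated with the others at 0.879 to 0.895, below the 0.962 between the CD133(+) and CD133(−) libraries numbered 4 themselves. Depth is argued against: after each library was thinned to 8344227 counts without the 5 small RNAs, the highest correlation between number 4 and another library was 0.898, below the lowest of 0.981 among the others. Gene length may contribute, since the ratio of number 4 to the others fell with length at a Spearman rho of −0.191 across 16010 genes, with medians of 0.31 in the shortest and −0.35 in the longest protein-coding genes of 3 equal groups. That value lies between the bounds set beforehand for a length bias and for its absence, so it stays open. The design gives no group that separates the numbers, so no biological explanation was tested.

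FGFBP2, whose locus (chromosome 4, 15960243 to 15969309) overlaps the end of PROM1, was higher in CD133(+) cells in DESeq2 with the block (log2 fold change 0.91, adjusted p = 0.0341). If a fixed share of PROM1 reads had been counted for FGFBP2, the ratio of their counts would be constant. It was 27.4 (95% exact interval 18.8 to 41.4) and 24.5 (18.9 to 32.4) in the CD133(−) and CD133(+) libraries numbered 4 and as low as 4.21 (3.63 to 4.91) in the others, a highest over lowest of 6.51. These intervals cover counting error only, and they lie apart, which argues against a fixed share as the whole source. Between CD133(+) and CD133(−) libraries of a pair the log2 ratio differed by −0.72 ± 0.61 (SD, n = 3 pairs). A share that varied between libraries and a difference of FGFBP2 with CD133 both stay open.

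Transcripts that differed by at least 4-fold at an unadjusted p under 0.05 in the lncRNA tables often lay inside protein-coding loci, as 28 of 54 did (51.9%), but so did 46.2% of the other tested transcripts (Fisher's exact p = 0.415). A candidate explanation for their size is that reads moved between overlapping features of a locus, in which case host genes would go the opposite way. Over 31 host genes the changes had a Spearman rho of −0.257 (permutation p = 0.163), with 19 of opposite sign. Some overlapping hosts share a transcript, such as CAST and ERAP1 (2.263 CPM for each). The permutation took the hosts as independent, which they are not. With transcript and gene both scaled to the gene-table total, the transcript at PLEKHA8 differed by −11.4 CPM and the gene by 2.83, and at DDR1 by 10.55 and −0.757. At ZNF445 the transcript differed by −27.2 CPM and the gene by 20.2, whereas at HELZ both were lower, by −52.7 and −6.77. Moved reads and a change of the transcripts themselves with CD133 cannot be told apart, because this correlation did not pass the threshold in either direction.

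With 3 against 3 libraries there are 10 splits, too few for a share under 0.05. The real split gave 0 changed genes and the highest other 3, and all 10 gave at least as many. For transcripts the real split gave 0 and the highest other 6, with 10 of 10 at least as many. With 0 in the real split, neither of these shares could come out otherwise, so they decide nothing. For gene lists the real split gave 10 and the highest other 11, with 2 of 10 as many or more, and for lncRNA lists 1 against 2, with 5 of 10. Splits that put both libraries numbered 4 on the same side gave 3276 to 3970 genes at an unadjusted p under 0.05 against 159 for the real split, which points to a structure of the samples, number 4 standing apart. The splits that set both libraries numbered 5 against both numbered 6 gave 83 and 102. Among the 4 splits that part all 3 pairs, also too few, DESeq2 with the block called 61 genes in the real split and at most 14 in the others, with 1 of 4 as large. For transcripts the same fit called 27 in the real split and 26, 20 and 20 in the others.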
